A study of Caenorhabditis elegans with 11 samples.

How the data were processed

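The samples were 5 libraries of AVK neurons and 6 libraries of whole L1 larvae, grouped by their titles. Nothing in the labels says that libraries came from separate cultures. Per the labels' protocols, embryos from bleached hermaphrodites hatched overnight into buffer, AVK cells marked with mCherry were sorted from dissociated larvae into Trizol, reference RNA came from larvae frozen in liquid nitrogen, and complementary DNA was made with a low-input SMART-Seq kit before Illumina sequencing. The authors deposited 1 table with an RPKM value per feature and library, per the file headers. Per the submitters' processing notes edgeR was used, with no version given. The aligner, counter, genome build, annotation and use of strand are not given in the sources used here. The deposited table also holds the authors' own comparison, namely a weighted difference (a score with no fixed range) and an FDR (an adjusted p-value), per the file headers. For 6992 of the 7782 features at an FDR under 0.05, the sign of the weighted difference in the authors' deposited table was opposite to the difference of mean RPKM, AVK minus reference, so it was read as reference minus AVK. No sample column was left unused.

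Feature names were matched to the Ensembl WBcel235 annotation and gene name tables. Of 46739 features, 41387 had the same name, 3232 matched by sequence name and 2120 did not match; of the 11377 tested, 11158 matched. Coordinates are those of that annotation, which may not be the build the authors used. RPKM are not counts, so no count test was run. RPKM times exon length moves in steps of whole reads, and the most frequent step gave each library's depth. Values of up to 20 reads were whole within 0.05 reads in 41.2 to 61.0% of cases, where chance gives 10.0%, so depths and shares of reads are approximate and reads were not recovered for a count test. In paired libraries the step was taken as a read, so that a pair counts for 2. Differences between libraries of a group were compared with counting noise as the mean chi-square per gene over genes with at least 20 estimated reads in each, ribosomal RNA left out.

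Features with at least 1 RPKM in at least 5 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a trend and robust variances, all 11 libraries, no covariate), two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The 34 gene lists, fixed before the data were examined, were the AVK genes, pan-neuronal synaptic, dense-core vesicle, FLP neuropeptides, NLP neuropeptides, insulin-like peptides, neuropeptide GPCRs, monoamine receptors, 4 transmitter identity lists, acetylcholine, glutamate and GABA receptors, potassium channels, calcium and sodium leak channels, innexins, homeobox genes, 11 lists of other cell types, ribosomal proteins, mitochondrially encoded genes, heat shock and stress, and histones. The 33 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. Of these, 12 passed, and 0 held with a correlation estimated per list. At an unadjusted p under 0.05 with the estimated correlation, 3 lists lay below it, the AVK genes, dense-core vesicle and heat shock lists. Camera ranked up, without passing, the monoamine receptors, GABA receptors, potassium channels, collagens, germline, and coelomocytes and excretory system, although their medians and means were negative. Adjusting over the list alone gave the counts of rises and falls reported over all genes, except 16 falls for insulin-like peptides, 29 for body wall muscle, 4 for germline and 26 for histones. The mean log2 level of each list per library was compared by an exact two-sided permutation test over 462 splits, whose smallest p is 0.0022; 26 of 34 lists passed after adjustment. The same number passed with the reference averaged in the 3 pairs that correlate most, where 56 splits allow no p under 0.018.

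Named genes followed a rule fixed before the data were examined. It takes each member of the AVK and transmitter identity lists, the 10 largest rises and 10 largest falls among named genes past the threshold whose groups do not overlap, for each other list up to 2 rises and 2 falls (or the 2 most abundant members where none passed), and the 10 most abundant genes in AVK. Any other gene named was chosen after its values were seen.

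Data were simulated with 50 of 11377 genes changed at each size and no shift common to all genes. The test recovered 12 and 10% of genes at log2 changes of 1 and -1, and 90 and 86% at 2 and -2. Of its calls, 3.9% were unchanged genes. These shares hold for that setting and not for the real comparison, where far more genes were called. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean RPKM of at least 5, 3 other scalings, group-specific variances, an exact rank permutation test, a test against a log2 fold of 1, each library left out, AVK replicates 1 and 2 or 3 to 5 alone, a replicate block and an estimated correlation. Chosen after seeing the data were 2 more scalings, read layout as a term, each layout alone, and the reference averaged in 3 pairs, also for list levels. Figures and other checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.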

Results

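RNA was sequenced from AVK neurons of Caenorhabditis elegans and from whole animals of the same larval stage. AVK is a pair of interneurons in the head that release FMRFamide-related peptides encoded by flp-1. The neurons carried a red fluorescent protein under a shortened flp-1 promoter and were isolated by fluorescence-activated sorting from dissociated, synchronised L1 larvae. There were 5 AVK libraries and 6 whole L1 reference libraries, the latter from larvae of the N2 wild-type strain frozen without dissociation, so strain and handling differ along with cell type. The comparison asks which transcripts are more or less abundant in AVK than in the whole larva. The values were RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library), and 11377 of 46739 features passed the filter of at least 1 RPKM in at least 5 libraries. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

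The column headers marked 3 AVK and 3 reference libraries as paired, and left 2 AVK and 3 reference libraries unmarked. This split is read as a technical batch, but the main fit held no term for it. With read layout as a term, an alternative chosen after the data were seen, 736 genes were higher and 7539 lower in AVK. Depth estimated from the steps in the low RPKM values ran from 18440000 to 55950000 reads in AVK (n = 5) and from 21050000 to 82540000 in the reference (n = 6). These depths are approximate, since only 41.2 to 61.0% of low values came out whole at the estimated step. AVK libraries listed 7482 to 10069 features at 1 RPKM or more, against 10172 to 13709 in the reference, so the ranges did not overlap. The 10 most abundant features took 53 to 73.3% of the RPKM sum in AVK and 17.1 to 50.6% in the reference. Ribosomal RNA genes took an estimated 3.66 to 7.60% of reads in AVK, 7.19 to 21.1% in the unmarked reference libraries and 42.8 to 59.9% in the paired ones. Correlations of log2 values across genes, which are not independent replicates, were 0.858 to 0.939 among AVK libraries, 0.873 to 0.981 among reference libraries and 0.583 to 0.713 between the groups. Reference libraries 1 and 4, 2 and 5, and 3 and 6 correlated at 0.975 to 0.981, above the 0.873 to 0.927 of the other reference pairs. The mean chi-square per gene on estimated reads was 28.1, 37.2 and 37.5 in those 3 pairs and 209 to 411 in the other reference pairs. Whether each pair holds the same RNA is not given in the labels. All 6 were counted as separate libraries, and p-values are too small if the pairs share their RNA. Averaging each pair, an alternative chosen after the data were seen, gave 486 genes higher and 7255 lower in AVK.

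**Figure D1:**
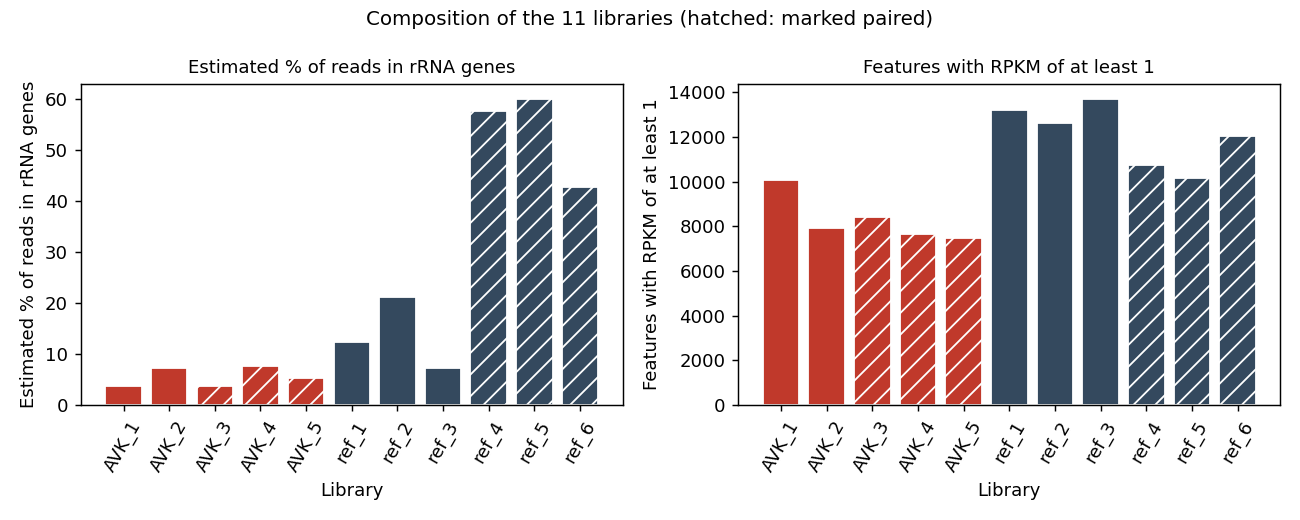
Estimated percentage of reads in ribosomal RNA genes (left) and number of features with at least 1 RPKM (right) in each of the 11 libraries. Bars are single libraries, red for AVK and dark for the whole L1 reference (ref), hatched where the header marks the library as paired; the ribosomal share reaches 42.8 to 59.9% in the 3 paired reference libraries and stays at or below 7.60% in AVK.

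By mean RPKM, the neuropeptide genes nlp-49 and flp-1 were the most abundant in the AVK libraries. The neuropeptide-like gene nlp-49, listed under its sequence name H05L03.3, had 156500 ± 70380 RPKM (SD, n = 5) in AVK and 553 ± 299 (SD, n = 6) in the reference, a log2 fold change of 8.19 ± 0.44 (SE; limma adjusted p = 2.861e-13). The gene flp-1, whose promoter marked the sorted cells and which is therefore not an independent result, had 137900 ± 46620 RPKM against 801 ± 439, a log2 fold change of 7.55 ± 0.43 (limma adjusted p = 4.651e-13). Both were higher in 5 of 5 AVK libraries than in any reference library. Fold changes here and below are on the log2(RPKM + 1) scale, which understates the change of low genes, and adjusted p-values are Benjamini-Hochberg values from limma. In the WBcel235 annotation, where genes were located by name, nlp-49 lies on chromosome X at 5904653 to 5905345 and flp-1 on chromosome IV at 9144705 to 9146128. The annotated span of flp-1 overlaps daf-10 on the opposite strand, and the sources used here do not say whether strand was used in counting.

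Of the 8 genes listed as AVK genes, 7 rose and 1 fell, with the same result when adjusted over the list alone and in all 6 scalings of the libraries. Besides nlp-49 and flp-1, the list holds the two-pore-domain potassium channel gene twk-47, which rose from 2.68 ± 2.03 RPKM in the reference to 227.5 ± 116.3 in AVK (log2 fold change 5.99 ± 0.42, limma adjusted p = 2.418e-11). The dopamine receptor gene dop-3 rose by 3.23 ± 0.37, the homeobox gene unc-42 by 2.99 ± 0.37, the nuclear receptor gene fax-1 by 2.67 ± 0.41 and the neuropeptide gene nlp-69 by 2.56 ± 0.56 on the log2 scale. The Pax6 homologue vab-3 went the other way, with 3.62 ± 0.90 RPKM in AVK and 32.9 ± 13.6 in the reference (log2 fold change -2.79 ± 0.36, limma adjusted p = 1.719e-07). The list was taken from general knowledge of AVK, and whether any entry rests on these same libraries was not established. The camera test placed the list above the other genes (adjusted p = 3.851e-15 with a preset correlation, adjusted p = 0.113 with an estimated correlation). Both the count of rises and the camera test include flp-1, whose promoter marked the sorted cells, and no test was run without it. The span of nlp-69 lies within that of sec-23, while those of dop-3 and twk-47 overlap only the ends of svh-2 and obr-4. Part of the reads of these genes could be shared.

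**Figure D2:**
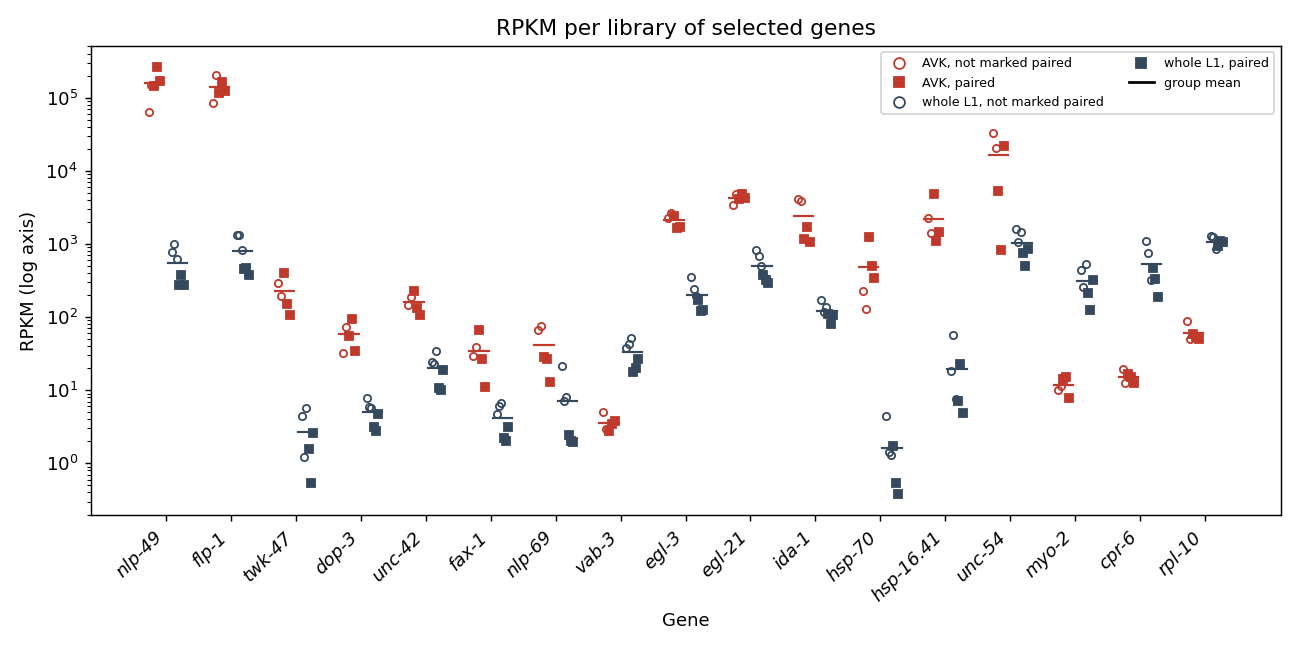
RPKM on a log axis of 17 genes in the 5 AVK (red) and 6 whole L1 (dark) libraries. Points are single libraries, open circles not marked paired and filled squares paired, and lines are group means; nlp-49 and flp-1 reach at least 62849 RPKM in each AVK library, whereas unc-54 in AVK replicate 4 lies within the reference range.

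Across all 11377 tested features, 580 were higher and 7304 lower in AVK, and 3493 did not pass limma's adjusted p of 0.05. The median log2 fold change was -1.24, so the direction of modest changes depends on how the libraries are scaled. After centring each library on its median, 3668 features were higher and 3027 lower, which moved the share of higher calls from 7.4% to 54.8%. Quantile normalisation gave 3400 higher and 3505 lower, and leaving ribosomal RNA and the 20 most abundant genes out of the library sums gave 1689 and 5440. In all 6 scalings, 358 genes were higher and 3026 lower. Within the unmarked libraries, 461 genes were higher and 6561 lower, and within the paired libraries 601 and 6046. Of the 120 named genes past the threshold, 113 were past it in both layouts. Each of the alike reference pairs is split between the layouts, so the layouts may share RNA and cannot be taken as independent checks. Many of the named genes were also picked for large changes over all libraries. All 120 had the same sign in both layouts, which was bound to hold for genes whose groups do not overlap. The groups did not overlap in 47.9% of features, where chance gives 0.43% for a single feature if the 11 libraries are independent. That chance value ignores the alike reference pairs and the shift shared by all features, which depends on scaling. The comparison is therefore not a test of single genes. The authors' deposited table holds an FDR and a weighted difference whose sign, judged from the RPKM, is reference minus AVK. At an FDR under 0.05 the authors' deposited table has 3261 features higher and 4521 lower in AVK. Among the features tested here the authors' deposited table has 2283 higher and 3303 lower. The 580 genes higher here were all among those higher in the authors' deposited table, and of the 7304 lower here 3285 were lower in the authors' deposited table, with 0 genes opposite in direction. After median centring 2265 higher and 2573 lower genes were shared with the authors' deposited table, with 0 opposite.

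Most genes of neuropeptide processing and dense-core vesicles were higher in AVK. Of 22 tested members, 15 rose, 2 fell and 5 did not pass, and 12 were higher in all 6 scalings. The proprotein convertase gene egl-3 had 2140 ± 447 RPKM in AVK and 200.7 ± 87.01 in the reference (log2 fold change 3.48 ± 0.37), and the carboxypeptidase E gene egl-21 had 4269 ± 560 against 498 ± 212 (3.19 ± 0.37). The vesicle membrane protein gene ida-1 rose by 4.09 ± 0.40, and pamn-1 and pgal-1, which encode enzymes of peptide amidation, rose by 3.76 ± 0.38 and 3.55 ± 0.39 on the log2 scale. With 11320 ± 1723 RPKM, pgal-1 was among the 10 most abundant genes of AVK. The peptidase genes nep-1 and cpd-1 fell, with log2 fold changes of -2.55 ± 0.38 and -2.07 ± 0.39, and cpd-1 did not pass with median centring (-0.75). The mean log2 level of the list was 6.45 ± 0.23 (SD, n = 5) in AVK and 4.81 ± 0.54 (SD, n = 6) in the reference (exact permutation p = 0.0022, two-sided, the smallest the test can give, adjusted 0.0049 over 34 lists). With the reference averaged in 3 pairs the exact permutation p was 0.018, the smallest that 56 splits can give, and adjusted 0.0243. The camera adjusted p was 3.789e-21 with the preset correlation and 0.19 with an estimated correlation.

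Of 36 pan-neuronal synaptic genes, 7 rose, 1 fell and 28 did not pass, and the list's median log2 fold change was 0.38, or -0.25 with ribosomal RNA left out of the sums. Besides egl-3 and egl-21, rab-3, unc-104, unc-33, unc-57 and unc-76 rose, though rab-3 and unc-33 did not pass with ribosomal RNA left out of the sums (log2 fold changes of 0.39 and 0.66), nor rab-3 with equal RPKM sums (0.75). The synaptogyrin gene sng-1 fell, with 1.57 ± 0.85 RPKM in AVK and 10.6 ± 3.82 in the reference. With ribosomal RNA left out of the sums 5 were higher and 10 lower, after median centring 34 and 1, and 5 were higher in all 6 scalings. Without AVK replicate 1 the median was 0.10, and without reference replicate 5 it was 0.16. With read layout as a term 12 rose and 1 fell, and with the replicate block 10 rose and 2 fell. The camera adjusted p was 3.262e-14, and adjusted p = 0.633 with an estimated correlation. The list level of 4.83 ± 0.54 in AVK against 4.31 ± 0.60 in the reference did not pass the exact permutation test (p = 0.182).

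Most other neuropeptide genes were lower than in the whole larva. Of 30 FLP neuropeptides tested, flp-1 alone rose and 27 fell with the RPKM as deposited, while flp-16 and flp-27 did not pass. With median centring and with quantile normalisation 3 FLP neuropeptides were higher and 22 lower, with ribosomal RNA and abundant genes left out 2 and 25, and in all 6 scalings 1 and 22. The gene flp-24 had 2.06 ± 0.70 RPKM in AVK and 32.5 ± 5.81 in the reference, and flp-19 had 15.8 ± 4.63 against 177 ± 79.4. The camera adjusted p was 0.0029, and adjusted p = 0.917 with an estimated correlation. Of 68 NLP neuropeptides, 5 rose, 57 fell and 6 did not pass. After median centring 11 NLP neuropeptides were higher and 37 lower, after quantile normalisation 11 and 41, and in all 6 scalings 5 and 37. Besides nlp-49 and nlp-69, those that rose were nlp-10 (402 ± 130 RPKM against 28.5 ± 7.74), nlp-50 and pdf-1, the last 2 named after their values were seen. The largest falls that passed were those of nlp-17, with a log2 fold change of -4.08 ± 0.39, and nlp-36, with -3.31 ± 0.37. Of 19 insulin-like peptides, 14 fell, ins-27, ins-29 and ins-33 did not pass, and ins-28 and ins-13 rose. The gene ins-28 had 75.0 ± 36.8 RPKM against 14.8 ± 8.81; ins-13 was listed at 2.42 to 9.41 RPKM in AVK and at 0 to 1 in the reference, and its span overlaps acdh-2. The lists of NLP neuropeptides and insulin-like peptides did not pass camera (adjusted p = 0.0854 and 0.243), though the former did without AVK replicate 2 (adjusted p = 0.0375), without reference replicate 6 (adjusted p = 0.0477) and within the paired libraries (adjusted p = 0.0309).

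Most genes of the transmitter identity lists were lower in AVK with the RPKM as deposited, though only 5 were lower in all 6 scalings. All 3 cholinergic genes (unc-17, cha-1 and cho-1), the glutamate transporter gene eat-4, and all 4 GABAergic genes (unc-25, unc-46, unc-47 and snf-11) fell. Of 7 monoaminergic genes tested, 6 fell (cat-1, cat-4, bas-1, dat-1, tdc-1 and tbh-1), and tph-1 did not pass, with 0.71 ± 0.36 RPKM against 1.26 ± 0.45. The genes cat-2 and mod-5 missed the filter, with means of 0.38 and 0.20 RPKM in AVK. The vesicular acetylcholine transporter gene unc-17 had 2.69 ± 1.10 RPKM in AVK and 15.6 ± 5.76 in the reference, and eat-4 had 1.42 ± 0.70 against 10.6 ± 5.79. The glutamate decarboxylase gene unc-25 was the most abundant of these in AVK, at 64.9 ± 21.7 RPKM against 201 ± 94.6. With median centring or quantile normalisation cho-1, unc-47, tbh-1 and tph-1 changed sign, tph-1 past the threshold in both and tbh-1 with median centring. The call of unc-47 was also lost without AVK replicate 2, 3 or 5 or reference replicate 1, 2 or 3 (log2 fold changes of -0.61 to -0.85), that of tbh-1 without AVK replicate 2 (-0.73) or 5 (-0.71), and those of both within each layout. Within a layout the calls of cho-1 (-0.77, paired) and snf-11 (-1.09, unmarked) were lost, and those of snf-11 and tbh-1 did not pass the exact rank permutation test (adjusted p = 0.0754 and 0.114). The cholinergic, GABAergic and monoaminergic lists did not pass camera (adjusted p = 0.52, 0.655 and 0.312), and the glutamatergic list of 1 gene was not tested.

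Individual receptor genes were higher in AVK, while the balance of rises and falls in their families depended on scaling. Of 80 neuropeptide GPCRs, 18 rose and 49 fell, with a median log2 fold change of -0.99 that became 0.33 after median centring and 0.20 after quantile normalisation, with 33 higher and 7 lower in the former and 30 and 12 in the latter. With the filter at a mean RPKM of at least 5, 25 neuropeptide GPCRs were tested, 13 rose and 9 fell, and the median was 0.91. The gene npr-40 had 37.7 ± 22.3 RPKM against 1.74 ± 0.89, and frpr-9 had 21.2 ± 12.3 against 2.08 ± 1.24, whereas npr-26 and npr-5 fell by 2.66 and 2.59 on the log2 scale. Camera placed this list above the other genes, although its median and mean were negative (adjusted p = 0.0054, and adjusted p = 0.917 with an estimated correlation). Of 19 monoamine receptors, 12 fell, 4 did not pass (dop-1, dop-2, dop-5 and mod-1) and 3 rose: dop-3, dop-4 and the octopamine receptor gene ser-3, the last with 124 ± 105 RPKM against 5.74 ± 2.95. The span of ser-3 lies within that of teg-4, which had a mean of 6.84 RPKM in AVK. Of 19 glutamate receptors and their auxiliary genes, glr-5, sol-2, mgl-2 and glc-3 rose, 8 fell, led by glc-1 (log2 fold change -3.77 ± 0.37) and glc-2, and 7 did not pass; the call of glc-3 was lost with ribosomal RNA left out of the sums (0.57). The glutamate receptor list had a median of -0.41, or 0.91 after median centring, 0.73 after quantile normalisation and 0.065 with ribosomal RNA and abundant genes left out (11 higher and 2 lower in the first and second, 8 and 6 in the last), and camera again placed it above the other genes (adjusted p = 0.0058, and adjusted p = 0.917 with an estimated correlation). With the filter at a mean RPKM of at least 5, 11 glutamate receptors were tested, 4 rose and 3 fell, and the median was 0.57; it was -0.22 without AVK replicate 5 and -0.17 without reference replicate 3. Of 8 GABA receptors, lgc-38 rose from 37.8 ± 16.7 to 347 ± 161 RPKM, gab-1, lgc-35, lgc-37 and exp-1 fell, and gbb-1, gbb-2 and unc-49 did not pass. With median centring and quantile normalisation lgc-35 changed sign (log2 fold changes of 0.28 and 0.077) and did not pass. In these scalings gab-1 did not pass (-0.017 and -0.14), lgc-37 changed sign and did not pass (0.41 and 0.089), and exp-1 changed sign and was past the threshold in the other direction (0.54 and 0.40). Of 24 acetylcholine receptors, gar-1 rose, 18 fell, led by lev-1 and eat-2, and acr-2, acr-12, acr-20, gar-2 and unc-38 did not pass. The medians of the monoamine and GABA receptor lists, -1.08 and -0.70, became 0.24 and 0.62 after median centring (9 higher and 1 lower, 5 and 0) and 0.16 and 0.52 after quantile normalisation (7 and 1, 5 and 0). The acetylcholine receptors had 5 higher and 4 lower after median centring and 4 and 7 after quantile normalisation, and gar-1 did not pass with ribosomal RNA left out of the sums (log2 fold change 0.82). The monoamine, GABA and acetylcholine receptor lists did not pass camera (adjusted p = 0.118, 0.243 and 0.655).

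Of 56 potassium channels, 11 rose, 37 fell and 8 did not pass. The counts were 19 higher and 14 lower after median centring and 18 and 17 after quantile normalisation, and 8 and 14 in all 6 scalings. After twk-47, the largest rise was that of twk-44, with 16.9 ± 8.88 RPKM against 0.38 ± 0.27, and the largest falls were those of kqt-2 and sup-9, with log2 fold changes of -3.27 ± 0.35 and -2.85 ± 0.38. Of 11 calcium and sodium leak channels, 1 rose and 10 did not pass. The gene that rose, nlf-1, which promotes surface localisation of the sodium leak channel, had 70.7 ± 61.5 RPKM against 11.8 ± 6.09. The list's median of 0.53 became -0.14 with ribosomal RNA left out of the sums, 0.15 without AVK replicate 1 and 0.27 without reference replicate 5. All 11 calcium and sodium leak channels were higher after median centring, while 4 rose without AVK replicate 4 and 3 without AVK replicate 5 or reference replicate 3. The camera adjusted p was 6.532e-07, or adjusted p = 0.633 with an estimated correlation. Of 21 innexins, the gap junction genes, unc-7 rose by 1.56 ± 0.37, 15 fell, led by inx-15 and inx-6, and 5 did not pass (inx-1, inx-7, inx-14, inx-19 and unc-9). Innexins had 6 higher and 10 lower after median centring, and 5 and 13 after quantile normalisation. Of 69 homeobox and related genes, 4 rose, 52 fell and 13 did not pass, against 18 higher and 25 lower after median centring and 16 and 26 after quantile normalisation. The homeobox genes that rose were ceh-30 (75.2 ± 40.3 RPKM against 3.88 ± 1.79), unc-42, zag-1 and ceh-5, the last 2 named after their values were seen. The largest falls were those of ceh-37 (log2 fold change -3.93 ± 0.36) and ceh-22 (-3.17 ± 0.36). The potassium channel, innexin and homeobox lists did not pass camera (adjusted p = 0.112, 0.312 and 0.44).

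Most markers of the other cells that a sort could hold, apart from germline genes, were lower with the RPKM as deposited. So were 7304 of all 11377 tested features, and a fall by itself does not set a list apart from other genes. All 9 pharyngeal muscle genes fell, and the myosin gene myo-2 had 11.7 ± 2.95 RPKM in AVK against 313 ± 149 and myo-1 8.53 ± 2.39 against 299.6 ± 206.9. Of 30 intestine genes, 29 fell and fat-5 did not pass; cpr-6 had 15.4 ± 3.02 RPKM against 528 ± 342 and spp-5 7.71 ± 1.76 against 229 ± 78.4. In all 6 scalings 8 pharyngeal and 23 intestine genes were lower. The camera adjusted p was 0.0029 for pharyngeal muscle and 4.248e-06 for intestine, and adjusted p = 0.668 for each with an estimated correlation. Of 32 body wall muscle genes 28 fell, among them mlc-2 and unc-15, 3 did not pass (ttn-1, unc-45 and unc-68) and unc-54 rose. The unc-54 myosin heavy chain gene had 33275, 20695, 5227, 826 and 21493 RPKM in AVK replicates 1 to 5 and 495 to 1579 in the reference (log2 fold change 3.25 ± 0.85, limma adjusted p = 0.0051), so AVK replicate 4 lay inside the reference range. The rise of unc-54 did not pass the exact rank permutation test (adjusted p = 0.0754), and its log2 fold change was 4.28 in the unmarked and 2.73 in the paired libraries. In all 6 scalings 12 body wall muscle genes were lower, with 12 after median centring and 17 after quantile normalisation. Body wall muscle missed the camera threshold (adjusted p = 0.112).

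Of 28 ciliated sensory neuron genes, 26 fell, led by bbs-8 and bbs-1, dyf-11 did not pass, and daf-10, which overlaps flp-1, rose. Of 10 touch neuron genes, 8 fell, led by mec-3 and mec-2, mec-6 did not pass, and the alpha-tubulin gene mec-12 rose to 788 ± 391 RPKM from 326 ± 171, a rise that did not pass in the unmarked libraries alone (log2 fold change 0.53), in AVK replicates 1 and 2 alone (1.13) or with ribosomal RNA left out of the sums (0.59). Of 11 ventral cord motor neuron genes, 8 fell, led by unc-3 and unc-4, and acr-2, acr-12 and unc-53 did not pass. Of 77 collagens, 47 fell, led by col-103 and col-39, and 5 rose: col-110 and col-187, with means of 9.22 and 3.30 RPKM in AVK, and col-8, col-36 and rol-8, of which col-36 and rol-8 did not pass with ribosomal RNA left out of the sums (log2 fold changes of 0.81 and 1.19). Hypodermis genes fell in 14 of 18 cases, led by grd-5 and let-805, and 4 did not pass (bli-4, elt-6, noah-1 and wrt-10). Glia genes fell in 8 of 9 cases, led by vap-1 and itx-1, and glt-1 did not pass. Of 12 germline genes, cgh-1, csr-1, mes-6, prg-1 and wago-1 fell and 7 did not pass; after median centring 7 were higher and none lower, as with quantile normalisation. The signs of cgh-1, mes-6 and wago-1 changed with median centring and quantile normalisation, none past the threshold. The sign of csr-1 changed with median centring (log2 fold change 0.15, not past the threshold), and its call was lost in the unmarked libraries and in the exact rank permutation test (adjusted p = 0.114). The germline median of -0.44 became 0.89 after median centring and 0.77 after quantile normalisation, and that of the motor neuron list, -1.28, became 0.044 and -0.043. Of 10 coelomocyte and excretory genes, 7 fell, led by vha-5 and ceh-6, exc-9 rose to 193 ± 162 RPKM from 16.9 ± 7.45, and cup-5 and exc-5 did not pass. With median centring the collagens had 10 higher and 13 lower, and with quantile normalisation 10 and 14; falls of collagens numbered 33 to 53 without single libraries. The other lists also had fewer falls with median centring, 15 for ciliated neurons, 5 for touch neurons, 2 for motor neurons, 10 for hypodermis, 5 for glia and 2 for coelomocytes and the excretory system. Falls in the germline list numbered 3 without AVK replicate 5 or reference replicate 1. Genes named here beyond 2 per list and direction were chosen after their values were seen. None of these 8 lists passed camera (the ciliated list did without reference replicate 5, adjusted p = 0.0469), with adjusted p-values of 0.112 (ciliated), 0.655 (touch), 0.948 (motor), 0.584 (collagens), 0.112 (hypodermis), 0.112 (glia), 0.113 (germline) and 0.655 (coelomocytes and excretory system).

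**Figure D3:**
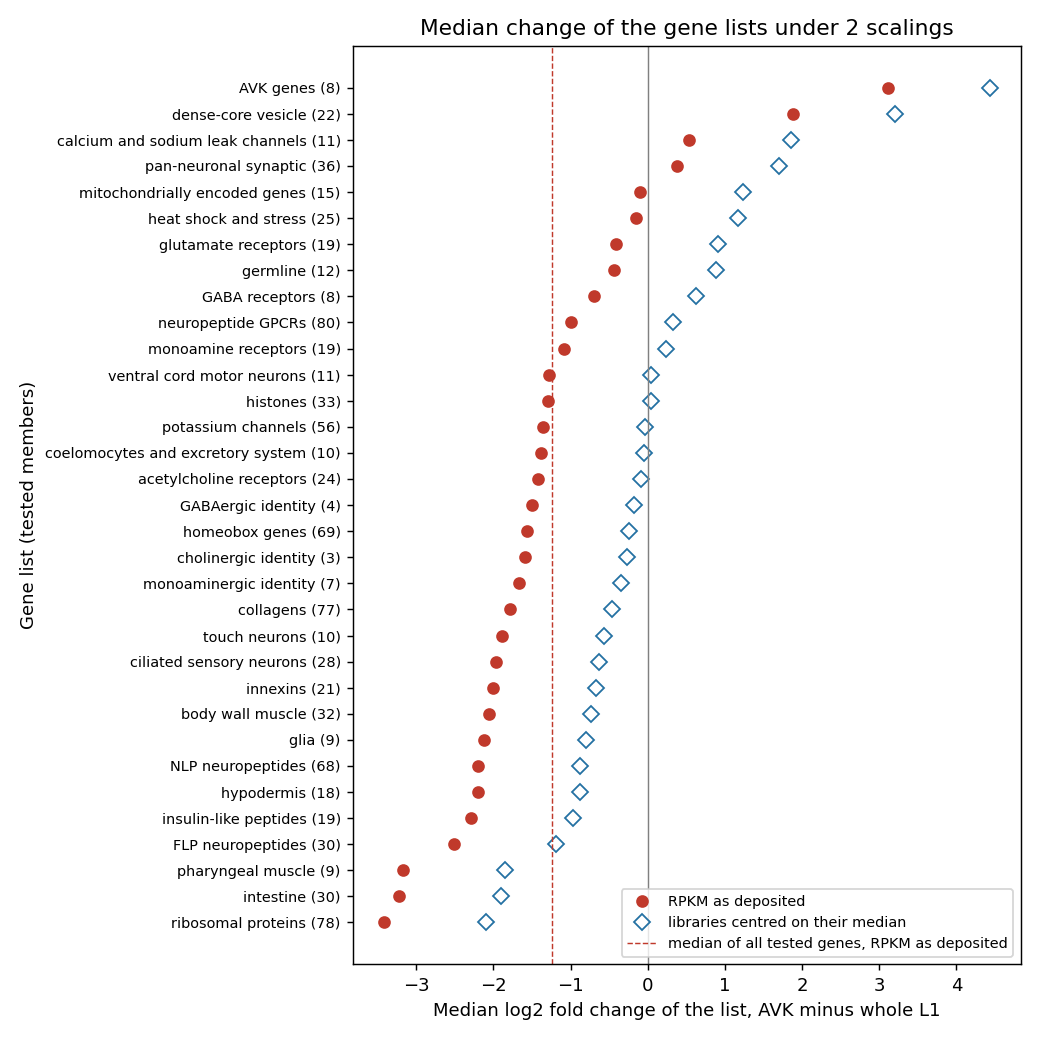
Median log2 fold change (AVK minus whole L1) of 33 gene lists with at least 3 tested members, given in parentheses. Filled circles use the RPKM as deposited and open diamonds the libraries centred on their median; the dashed line at -1.24 is the median of all tested genes, and the AVK genes and ribosomal proteins lie at the ends of both series.

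Ribosomal protein transcripts were far lower in AVK, and the hsp-16 genes and hsp-70 far higher, while other heat shock and stress genes rose, fell or did not pass. Of 78 ribosomal protein genes, 77 fell and rpl-42 rose, and 76 were lower in all 6 scalings. The gene rpl-10 had 60.2 ± 15.6 RPKM against 1074 ± 168, and rpl-41 had 15.8 ± 11.4 against 280.3 ± 59.39, whereas rpl-42 had 23.7 ± 17.8 against 0.24 ± 0.28. The list level was 4.92 ± 0.41 in AVK and 8.21 ± 0.34 in the reference (exact permutation p = 0.0022, or 0.018 with the reference averaged in 3 pairs), and the camera adjusted p was 9.803e-18, or adjusted p = 0.668 with an estimated correlation. Of 25 heat shock and stress genes, 9 rose, 10 fell and 6 did not pass. The small heat shock gene hsp-16.41 had 2217 ± 1549 RPKM against 19.6 ± 19.5 (log2 fold change 6.99 ± 0.54), and hsp-70 had 485 ± 443 against 1.65 ± 1.49 (7.25 ± 0.48). The span of hsp-70 lies within that of uggt-2, which had a mean of 5.82 RPKM in AVK. The near-identical pairs hsp-16.48 and hsp-16.49 and hsp-16.1 and hsp-16.11 rose by 5.87 to 6.56 on the log2 scale, and the hsp-70 family genes F44E5.5 and F44E5.4 had 55390 ± 30640 and 25980 ± 14740 RPKM against 263.4 ± 248.7 and 141.4 ± 105.9, but reads cannot be assigned surely within each pair. The metallothionein gene mtl-1 and the glutathione S-transferase gene gst-4 fell, with log2 fold changes of -5.08 ± 0.40 and -3.71 ± 0.48. The median of the heat shock and stress list was -0.15 and its mean 0.97. The median was 1.17 with median centring and 1.10 with quantile normalisation (14 higher and 4 lower in both), 0.73 with ribosomal RNA and abundant genes left out of the sums (12 and 6), -0.81 with ribosomal RNA alone left out and -0.51 with equal RPKM sums. With the filter at a mean RPKM of at least 5, 22 were tested, 9 rose and 8 fell, and the median was 0.40. In total, 8 members were higher and 4 lower in all 6 scalings, and camera placed it above the other genes (adjusted p = 4.29e-08, and adjusted p = 0.5 with an estimated correlation). AVK cells were dissociated and sorted and the reference larvae were not.

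None of the 15 mitochondrially encoded genes passed limma in either direction, with a median log2 fold change of -0.10. After median centring 9 were higher and the median was 1.23. With ribosomal RNA left out of the sums 4 were lower, none was higher and the median was -0.79, and with equal RPKM sums it was -0.43. Without AVK replicate 3 the median of the mitochondrially encoded genes was 0.29. The most abundant, nduo-6 and ctc-2, had 6699 ± 4812 and 6117 ± 5037 RPKM in AVK and 3841 ± 2523 and 3334 ± 2056 in the reference. Within layouts their sign differed, with -0.35 and -0.75 in the unmarked and 1.58 and 1.79 in the paired libraries, none past the threshold. Camera placed this list above the other genes although its median and mean were negative (adjusted p = 0.001, adjusted p = 0.205 within the unmarked libraries, and adjusted p = 0.917 with an estimated correlation). Of 33 histone genes, 25 fell, led by his-25 and his-11, his-41 rose, and 7 did not pass (camera adjusted p = 0.574); histone copies are nearly identical, so single members are uncertain. The call of his-41 was lost without AVK replicate 2 (log2 fold change 0.88), without reference replicate 5 (0.88), in AVK replicates 3 to 5 alone (0.73), in the unmarked libraries (0.95), with equal RPKM sums (0.69) and with ribosomal RNA left out of the sums (0.33). After median centring 3 histones were higher and 5 lower, and the histone median of -1.29 became 0.037. The 18S ribosomal RNA genes rrn-1.1 and rrn-1.2, also among the 10 most abundant, had 27480 ± 9933 and 27490 ± 9970 RPKM in AVK and did not pass (log2 fold changes of 0.024 and 0.023). Both were lower and past the threshold with quantile normalisation (-1.51 and -2.34) and with ribosomal RNA left out of the sums (-0.73 each).

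Among the largest rises with a gene name and no overlap between groups was spp-24, listed as F23F1.7, with 1850 ± 1058 RPKM against 29.1 ± 18.9. The largest falls were those of the 26S ribosomal RNA gene rrn-3.1 (-5.22 ± 0.78), hpo-15 (-5.08 ± 0.38), mtl-1, the lectin gene clec-17 (-4.99 ± 0.43), ttr-49 (-4.96 ± 0.37), the transporter gene haf-4 (-4.94 ± 0.37), clec-65 (-4.93 ± 0.35), the protease gene asp-14 (-4.91 ± 0.38), bcf-1 (-4.91 ± 0.38), listed as F57F4.4, and dao-6 (-4.90 ± 0.64). For rrn-3.1 the log2 fold change was -2.76 in the unmarked and -7.31 in the paired libraries. The span of hpo-15 overlaps nhr-47.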

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

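The tests of scaling and of dissociation for the heat shock genes, of depth for the lower genes, and of splits with the reference averaged in 3 pairs, were chosen after the result was seen. Of 330 groups of libraries examined for a value far from the others, 7 held one, where chance gives about 16.5. That chance value takes groups and libraries as independent. Lists share members with the named genes, and alike reference pairs make a single reference value less likely to stand out. The comparison with chance is therefore not a test of library quality. In AVK replicate 1 the mean log2 level of the touch neuron list was 3.38 (2.68 to 2.88 in the others), that of the ribosomal proteins 5.62 (4.61 to 4.88), log2(RPKM + 1) of rpl-10 was 6.47 (5.67 to 5.90) and of let-805 1.01 (0.43 to 0.57), and the 10 most abundant features took 53% of the RPKM sum (67.7 to 73.3%). In AVK replicate 5 log2(RPKM + 1) of mec-2 was 0.61 (1.83 to 2.26 in the others). In reference replicate 2 that of ins-13 was 1.0 (0 to 0.18).

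The myosin heavy chain gene unc-54 was among the 10 most abundant transcripts of AVK although other muscle genes were low. Muscle cells or free muscle RNA would bring their other abundant transcripts, but the median log2 fold change of the other 31 body wall muscle genes was -2.07 (SD 0.75, highest -0.19), against 3.25 for unc-54, which argues against that source as the whole cause. A candidate explanation that stays open is reads from the 3′ end of unc-54 in the reporter construct, since that sequence is commonly used in worm transgenes; the labels do not say whether it was used, and values per gene do not show where reads fall. AVK replicate 4, at 826 RPKM, stays within the reference range, and the reference larvae are of the N2 strain, which the labels give no reporter.

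The hsp-16 genes and hsp-70 were higher in 5 of 5 AVK libraries than in any reference library. Scaling does not account for this, as the lowest median log2 fold change of these 7 genes over 6 scalings was 5.8 (SD 0.63), nor does read layout, where the lower of the within-layout medians was 5.61 (SD 0.38). Their mean log2 level in the lowest AVK library lay 4.26 above that of the highest reference library. Stress during dissociation and sorting may be the source, but it cannot be told apart from a difference of the neuron itself, because each AVK library was dissociated and sorted and no reference library was; the strain differs in the same way.

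Most genes were lower in AVK, with 7304 lower against 580 higher. In 1 of 100 splits of the libraries, the real one, 7884 genes were called, and the highest other gave 5300. These splits treat the 6 reference libraries as independent, although 1 and 4, 2 and 5, and 3 and 6 are alike. With the reference averaged in 3 pairs, 1 of 56 splits, the real one, gave 7741 genes and the highest other gave 9. No other split examined called as many genes in either form, where 1 of 100 and 1 of 56 are the smallest shares possible. Each other split mixes AVK and reference libraries in at least 1 group, which widens the spread within it. The split that gave 5300 genes kept all AVK libraries in the same group. Whether libraries of a group share a culture or RNA is beyond these splits. Leaving ribosomal RNA and the 20 most abundant genes out of the sums moved the median log2 fold change from -1.24 to -0.59 (-0.69 to -0.54 without each library in turn), whereas leaving out ribosomal RNA alone moved it the other way, to -1.73. The genes left out may account for part of the shift and not for all of it, and ribosomal RNA works against it. The 20 were ranked with ribosomal RNA genes included, and no other number was tried. Whether further abundant genes account for the rest was not tested. Whether depth plays a part was not settled. In 6 of 6 pairs where an AVK library had more estimated fragments than a reference library, it listed fewer genes at 1 RPKM or more. Any pair had to give this, since AVK libraries listed at most 10069 such features and reference libraries at least 10172. A neuron that uses fewer genes than the whole animal remains open and was not tested.

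For the gene lists, 36 of 100 splits, the real one included, passed at least as many lists as the real one, 12. The highest other split gave 17. Other splits can still carry part of the AVK difference, and the one that kept all AVK libraries in the same group passed 15 lists. These splits therefore cannot settle the question. Chance is not excluded for the number of lists that passed camera with its preset correlation.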

How the results depend on the processing

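The scalings that leave out ribosomal RNA, the layout term, the single layouts and the averaged reference pairs were chosen after seeing the data. Genes higher in AVK numbered 580 and, under alternatives more than 1.5 times away, 3400 (quantile normalisation), 3668 (median centring), 217 (test against a log2 fold of 1), 359 (ribosomal RNA left out of the sums) and 1689 (ribosomal RNA and 20 abundant genes left out). Genes lower numbered 7304, and 4041 with a mean RPKM of at least 5, where 6371 genes were tested, 3505 with quantile normalisation, 3027 with median centring and 3514 in the test against a log2 fold of 1. The 580 genes all stayed higher under quantile normalisation, median centring and with ribosomal RNA and 20 genes left out, scalings that move the fold changes up. With scalings that move them down, 453 of the 580 stayed higher with equal RPKM sums and 359 with ribosomal RNA left out. Leaving out each library gave 506 to 656 higher, 6781 to 7821 lower and 12 to 13 lists. Gene lists past camera numbered 12, 19 with median centring and 0 with an estimated correlation. Levels of 26 lists differed, 28 with a pseudocount of 0.1 and 26 with the reference averaged in 3 pairs. Apart from the estimated correlation and the filter, the cause was not tested.

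For genes named by the rule fixed beforehand and called in either of the settings compared, signs changed with 3 scalings. With median centring the log2 fold changes were 0.077 (cho-1), 0.15 (csr-1), 0.28 (lgc-35), 0.48 (tbh-1), 0.92 (tph-1) and 0.47 (unc-47). With quantile normalisation they were 0.055 (cho-1), 0.077 (lgc-35), 0.30 (tbh-1), 0.74 (tph-1), 0.42 (unc-47), -1.51 (rrn-1.1) and -2.34 (rrn-1.2), and camera ranked the mitochondrially encoded genes down instead of up (median -0.21 against -0.10). With ribosomal RNA left out rrn-1.1 and rrn-1.2 both had -0.73, and both were past the threshold there and with quantile normalisation. The cause was not tested. Medians of gene lists also changed sign with other scalings, as given beside each list; leaving out ribosomal RNA and 20 abundant genes turned those of the GABA receptors (0.027), glutamate receptors (0.065), germline (0.13), heat shock and stress (0.73) and mitochondrially encoded genes (0.86) positive. Without single libraries the median of the mitochondrially encoded genes ran from -0.33 to 0.29 and that of heat shock and stress from -0.43 to 0.12.

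The numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.06, 0.30, -0.04, 0.01 and 0.16. With the replicate block 639 genes were higher, 7723 lower and 13 lists passed. The simulation recovered 12 and 10% of changes of 1 and -1 on the log2 scale. Few of its genes were changed, so these shares do not carry over to the real comparison. Genes that did not pass are still not shown to be alike, since failing the test does not show that a gene is unchanged.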

Other observations

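Beyond the genes fixed by the rule, several regulatory genes rose, chosen after their values were seen. The basic helix-loop-helix gene hlh-15 had 84.7 ± 74.7 RPKM (SD, n = 5) in AVK and 1.74 ± 0.94 (SD, n = 6) in the reference (log2 fold change 4.61 ± 0.45, SE), the nuclear receptor gene nhr-6 had 290.5 ± 258 against 8.47 ± 5.11 (4.68 ± 0.48), and mef-2 had 90.5 ± 60.4 against 4.21 ± 1.54 (3.96 ± 0.39). The sulfatase gene sul-2 had 839 ± 349 against 20.5 ± 6.44 (5.24 ± 0.36), and sbt-1, a neuroendocrine chaperone of the convertase egl-3, had 10170 ± 1534 against 1170 ± 575 (3.25 ± 0.39).

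The test that follows was chosen after the result was seen. With only the tested genes put in order along the chromosomes, genes that rose lay next to each other more often than random placement gives. Untested genes may lie between such neighbours, and no limit of distance was set. Among 560 located genes that rose there were 80 neighbouring, non-overlapping pairs, against a median of 24 and a highest value of 43 in 10000 random sets of tested genes. The longest run, on chromosome II at 3898142 to 3908516 (WBcel235), holds 6 tested features: F53C3.6, the pseudogene F53C3.5, F53C3.4, F53C3.3, F53C3.11 and fbxb-103. Their log2 fold changes were 4.07, 4.72, 5.34, 4.34, 2.29 and 3.64. Around flp-1 on chromosome IV, at 9136933 to 9148579, daf-10, rpb-12 and aly-2 rose as well, by 2.06, 1.29 and 1.10. Shared operons, tandem copies with similar sequence and reads running past gene ends are hypotheses that could give such neighbours, and these were not tested.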
